A study of Mus musculus with 8 samples.

How the data were processed

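Messenger RNA of the colon of 8 mice was measured, 4 wild type and 4 with a conditional Arg1 deletion, all on day 10 after the start of DSS. Per the labels' protocols, libraries were made from 1000 ng of total RNA with Illumina's stranded mRNA kit. Per the submitters' processing notes, the tools were BWA 0.7.14-r1136, STAR 2.5.2b, Subread 1.5.3 with featureCounts, and DESeq2 1.16.1, on the genome build GRCm38; the notes give no order or options, and the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited a single table of regularised log2 values (rlog) per gene and library, which are counts scaled for library size, put on a log2 scale and drawn toward each gene's mean, more so for genes with few reads. That shrinkage makes differences of weakly expressed genes too small, and it also lowers their spread. Counts cannot be recovered from these values, so the depth per library is unknown and no interval for counting error can be given. All 8 columns were matched to samples by the label that names each column, and no column was left unused.

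Genes were named by Ensembl ID from GENCODE vM21, which is on GRCm38, the build in the submitters' notes; 53274 of 53465 IDs had a symbol, and 19 of the tested genes had none. Coordinates are 1-based on that build. Transcript length and GC share were taken from the longest transcript of each gene, which was found for 16361 of the 16380 tested genes.

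Samples were grouped by the genotype in their labels. Replicate numbers follow the order of deposit and do not pair samples. Each library is labelled as a separate sample and the protocol speaks of mice, so p-values measure the spread between these samples. No pair of libraries was closer than 23.8 in Euclidean distance over the tested genes, and none was treated as a duplicate. Fixed before the data were examined were the tests, the filter, 38 gene lists, the rule for named genes and a set of alternatives. Genes with a mean rlog of at least 3 that were not constant were tested with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a prior that follows the mean, a group term and no covariate, two-sided, with Benjamini-Hochberg adjustment at 0.05. Arg1 was also tested by an exact two-sided permutation of the 70 assignments. The separation of the groups was the mean Euclidean distance between groups minus that within groups, against the 35 splits. A test of the difference in spread was not among those fixed beforehand. It took the mean distance within wild type minus that within Arg1 ko, against the 70 assignments.

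The lists were tested with limma's camera (preset correlation 0.01, moderated statistics, variance trend), adjusted over 37 lists with at least 5 tested members, the sex-linked list being reported but left out. Camera with an estimated correlation and limma's fry were run beside it. Camera compares a list with the other genes, and fry asks whether the genes of a list move on balance one way. Of 843 distinct list symbols 842 were matched to the file. Members are counted past the test over all genes and adjusted over the list alone.

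The genes named are Arg1, Arg2, Nos2 and Odc1, whatever their values. Named too are, in each direction, the 12 genes of largest difference among those past the threshold with non-overlapping groups, filled up to 6 by the smallest unadjusted p where fewer pass. Immunoglobulin and T-cell receptor segments, predicted genes, clones and pseudogenes are left out there. Of each list described, up to 4 members are named, those with the smallest p or, for cell types, with the highest mean. A gene that this rule names among the list members is not reported here. A test on simulated data used the real gene means and residual SDs with independent normal noise and 200 changed genes among 16380. For Arg1 ko against wild type it recovered 23.9% of genes changed by 0.5, 79.1% of those changed by 1 and 98.5% of those changed by 2 on the log2 scale, with 13 calls among unchanged genes. Residuals in the real libraries are shared between genes, which the simulation leaves out. It also gives both groups the same SD for a gene, while the real median SD was 0.258 in wild type and 0.096 in Arg1 ko.

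The alternatives chosen at that stage were no filter, a mean of at least 5, aligned library medians, quantile normalisation, limma's array weights, leaving out each library, a single prior variance, robust moderation, an adjusted p of 0.1, a difference of at least 1, other distances and gene sets for the separation, and other list tests. Chosen after seeing the data were a correction for transcript length, or for length and GC (natural splines with 5 degrees of freedom fitted to each library's deviations), fits without wild type 1 and 2 or without wild type 1 and 4, and list tests with an estimated correlation after leaving out each library or after quantile normalisation. Further lists drawn up once the data had been seen were 9 sets of genes of other tissues, clock, glucocorticoid and ribosomal genes. A sex covariate was not fitted, since Y-linked genes were expressed in all 8 libraries. Figures were drawn with matplotlib 3.10.9.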

Results

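RNA from the colon of 8 mice with chemically induced colitis was sequenced, 4 from mice carrying a conditional, cell-specific deletion of Arg1 and 4 from littermates that kept the gene. Arg1 encodes arginase 1, which splits arginine into ornithine and urea. Dextran sulfate sodium (DSS), a polymer that injures the colon epithelium, was given at 2.5% in the drinking water for a week, and plain water followed until day 10. The mice were 7 to 12 weeks old and matched for age and sex. The labels do not name the cell type in which Arg1 was deleted. The tissue is labelled as colon, while the protocol describes epithelial aggregates released with 30 mM EDTA. The deposited values are regularised log2 values (rlog) of 53465 genes, of which 24860 were listed at 0 in all 8 libraries and 16380 had a mean of at least 3 and were tested. The depth of each library is unknown, since rlog values keep no counts, and rlog pulls differences of weakly expressed genes toward 0. Differences are given below as Arg1 ko minus wild type on the rlog scale. The sample numbers in the labels form separate runs for the genotypes, and whether these mark batches is not given in the sources used here, so batch and genotype could not be separated.

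Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484 on the minus strand, GRCm38) was measured first in each library, because the deleted gene checks the labels. Its rlog value was 5.59, 5.57, 5.02 and 5.58 in the libraries labelled wild type 1 to 4, and 5.06, 4.87, 5.15 and 5.19 in the libraries labelled Arg1 ko 1 to 4. The means were 5.44 ± 0.28 (SD, n = 4) and 5.07 ± 0.14 (SD, n = 4), a difference of -0.37 with a standard error of 0.15. The library labelled wild type 3 lay inside the ko range, so its Arg1 value does not bear out its label. It is called the library labelled wild type 3 throughout. The deletion is conditional, so Arg1 RNA of cells without it may remain, and this value alone does not fix the genotype. The difference did not pass the test over all genes (limma adjusted p = 0.522), and an exact two-sided permutation test over the 70 assignments gave p = 0.114, where 0.0286 is the smallest value possible. Without the library labelled wild type 3 the difference was -0.51, with a limma adjusted p of 0.0418 (range over the alternatives 1.51e-04 to 0.872). The lowest of that range came with array weights, a fit whose weighting stopped before convergence and whose wild-type side is close to a single library. Leaving out the wild-type library with the lowest Arg1 enlarges the difference by construction, so the adjusted p of 0.0418 is no independent check of the deletion. Arg1 was weakly expressed, with a mean above that of 16.8% of the tested genes, and which exons the deletion removes is not given in the sources used here.

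The list of arginine, polyamine and nitric oxide metabolism genes asked whether the pathway around arginase differed. Of its 35 tested members, 14 were higher and 21 lower in Arg1 ko, with a mean difference of -0.03, no member past the gene test over all genes or adjusted over the list alone, and a limma camera adjusted p of 0.264. Without wild type 4 the mean was -0.08 and the list was called lower at the preset correlation (adjusted p = 0.0199; range over the alternatives 0.0199 to 0.792) but not with an estimated one (adjusted p = 0.479 with an estimated correlation), and without wild type 1 the mean was 0.012. Arg2, the mitochondrial arginase, had 10.79 ± 0.29 (SD, n = 4) in wild type and 10.53 ± 0.13 (SD, n = 4) in Arg1 ko. Nos2, the inducible nitric oxide synthase that competes for arginine, had 7.26 ± 0.60 (SD, n = 4) and 7.23 ± 0.39 (SD, n = 4), a difference of -0.04 that turned positive without the library labelled wild type 3 (0.25). Odc1, which makes the polyamine putrescine from ornithine, had 11.74 ± 0.28 (SD, n = 4) and 11.82 ± 0.08 (SD, n = 4), a difference of 0.08 that turned negative without wild type 4 (-0.04). The members with the smallest p were Oaz2 (-0.28), an inhibitor of ornithine decarboxylase, Sat1 (-0.43), which acetylates spermidine and spermine for breakdown, Arg1 itself, and Cps1 (0.87, and 0.51 without Arg1 ko 3), the urea cycle enzyme carbamoyl phosphate synthetase.

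Over all genes, no gene differed between Arg1 ko and wild type (limma, 0 of 16380 with an adjusted p under 0.05; smallest adjusted p 0.522). At an unadjusted p under 0.05 there were 1490 genes, 774 higher and 716 lower in Arg1 ko, where 819 would be reached by chance with independent genes. The 4 ko values lay entirely above the 4 wild-type values in 386 genes and entirely below them in 274, together 4.03% of the tested genes against 2.86% by chance. The count rests on the library labelled wild type 3: without it limma called 1005 genes, 467 higher and 538 lower in Arg1 ko. All had the direction seen with 8 libraries, which was nearly fixed in advance, since the fits share all other libraries. With array weights 10836 genes were called, but the weighting stopped before convergence. It gave wild type 2 a weight of 16.4 against 0.135 to 0.304 for the other wild-type libraries, so the wild-type side of that fit is close to a single library.

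None of the genes named next passed the test over all genes with 8 libraries (limma adjusted p = 0.522 for each). They have the smallest unadjusted p in each direction, and in each the 4 ko values lay apart from the 4 wild-type values. On the higher side were 3 fibrillar collagen chains of the connective tissue matrix. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) had 10.77 ± 0.37 (SD, n = 4) in wild type and 11.61 ± 0.12 (SD, n = 4) in Arg1 ko, a difference of 0.83 with a standard error of 0.17. Col3a1 differed by 0.70 and Col1a2 by 0.57. Ahcyl2, a regulator of ion transporters, differed by 0.54, Chp2, a cofactor of sodium-proton exchangers, by 0.53, and Rtl10, a retrotransposon-derived gene expressed near the filter, by 0.47. On the lower side, Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466), a secreted antibacterial lectin, had 16.96 ± 0.32 (SD, n = 4) in wild type and 15.78 ± 0.50 (SD, n = 4) in Arg1 ko, a difference of -1.18 with a standard error of 0.26. Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656), a transcription factor of endothelium and resting lymphocytes, went from 9.71 ± 0.13 (SD, n = 4) to 9.08 ± 0.12 (SD, n = 4), a difference of -0.63. The others were the immediate early genes Ier2 (-0.67) and Junb (-0.53), Cxcl13 (-0.61), a chemokine that attracts B cells, and Cebpd (-0.53), a transcription factor of the acute phase. Without the library labelled wild type 3, 11 of these 12 genes passed, with Chp2 the exception. In most of them, Col1a1, Col1a2 and Reg3b included, that library was the wild-type one nearest to the ko values. Leaving it out enlarges those differences by construction, so these passes are no independent check.

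**Figure D1:**
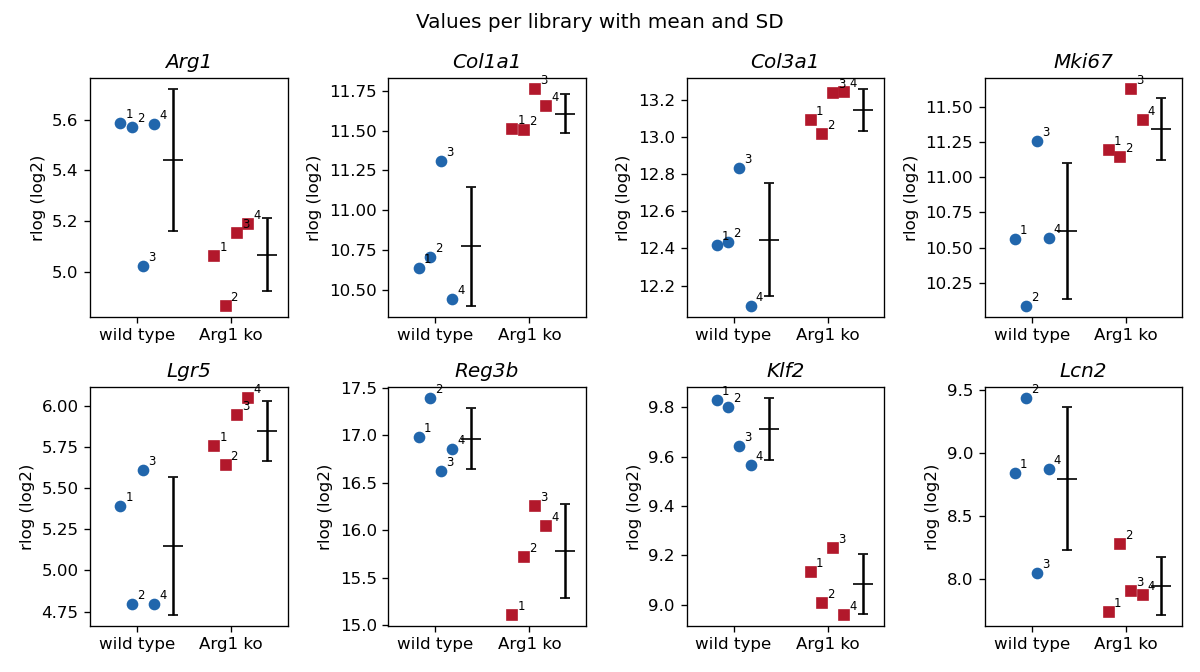
Rlog values (log2, vertical axes, each with its own range that does not start at 0) of 8 genes in the 4 wild-type libraries (circles) and the 4 Arg1 ko libraries (squares); digits give the library number, and the dash with bars beside the points is the group's mean with its SD. Library 3 of the wild type lies at 5.02 for Arg1, inside the ko range, and at 16.63 for Reg3b, above all 4 ko libraries.

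The gene lists fixed in advance asked whether pathways and cell types moved as groups. With limma camera at its preset correlation of 0.01, 15 of 37 lists passed an adjusted p of 0.05, 5 higher and 10 lower in Arg1 ko. With a correlation estimated from these data none passed (smallest adjusted p = 0.355), nor did any with fry, which tests each list by itself (smallest adjusted p = 0.144). Not a single member of any list passed the gene test over all genes. Of the 15 calls 12 stood without the library labelled wild type 3. Without wild type 1 and 2, a choice made after seeing the data, 7 stood, and the means of the oxidative phosphorylation (0.02) and inflammatory cytokine (0.02) lists turned positive. The highest adjusted p over the 17 alternatives of scaling, filter, weights and libraries was under 0.05 for cell cycle, fibroblast, acute phase and regenerating epithelium genes. It was 0.0881 for antimicrobial, 0.28 for red blood cell, 0.069 for stem cell, 0.452 for interferon, 0.721 for neutrophil, 0.0514 for cholesterol and 0.967 for cytokine genes. It was 0.491 for oxidative phosphorylation, 0.206 for enteric neuron, 0.587 for immediate early and 0.721 for fatty acid oxidation genes.

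The lists of fibroblast and matrix, cell cycle, stem cell and cholesterol synthesis genes were called higher in Arg1 ko at the preset correlation only. Of 24 fibroblast and extracellular matrix genes 21 were higher, by a mean of 0.26 (limma camera adjusted p = 7.31e-06; adjusted p = 0.355 with an estimated correlation), and 7 passed when adjusted over the list alone, all collagens. Besides Col3a1, its members of highest expression were Postn (0.30) and Sparc (0.22), both secreted matrix-associated proteins, and Dcn (-0.11), a collagen-binding proteoglycan. Of 33 cell cycle genes 31 were higher, by a mean of 0.35 (limma camera adjusted p = 2.12e-08, and 0.654 with an estimated correlation), and none passed adjusted over the list alone. This list also varied within the wild type, from -0.48 in wild type 4 to 0.24 in wild type 1, with the ko libraries between -0.03 and 0.48. The proliferation marker Mki67 had 10.62 ± 0.48 (SD, n = 4) in wild type and 11.34 ± 0.22 (SD, n = 4) in Arg1 ko, and Kif20a, Top2a and Foxm1 differed by 0.68, 0.58 and 0.56. Of 17 intestinal stem and Wnt target genes 16 were higher, by a mean of 0.24 (limma camera adjusted p = 0.00101; adjusted p = 0.444 with an estimated correlation) and none passed adjusted over the list alone. Lgr5, the receptor that marks crypt base stem cells, differed by 0.70, the Wnt target Axin2 by 0.58, Ephb3 by 0.39 and Cd44 by 0.30; the call was lost after a correction for transcript length alone, chosen after seeing the data (adjusted p = 0.0502). Of 22 cholesterol synthesis genes 19 were higher, by a mean of 0.14 (limma camera adjusted p = 0.00165; adjusted p = 0.542 with an estimated correlation), with none past adjusted over the list alone. Idi1, Hmgcs1 and Sqle differed by 0.44, 0.30 and 0.23. The call was lost without the library labelled wild type 3 (adjusted p = 0.0514), and the mean was 0.09 without Arg1 ko 3.

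The type I interferon list was called higher as well, at the preset correlation only, but varied widely within the wild type. Of its 29 members 28 were higher, by a mean of 0.26 (limma camera adjusted p = 0.00101; adjusted p = 0.901 with an estimated correlation), and none passed adjusted over the list alone. The list mean was 0.59 in wild type 1 and -0.73 in wild type 4, with the ko libraries between -0.09 and 0.30. Stat2, a signal carrier of the interferon receptor, differed by 0.53, Oas3 by 0.52, Parp14 by 0.46 and the RNA sensor Ifih1 by 0.33. The mean difference was 0.06 without wild type 4, where the call was lost (adjusted p = 0.452), 0.50 without wild type 1 and 0.15 without wild type 2.

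The lists of acute phase, antimicrobial and regenerating epithelium genes were called lower in Arg1 ko at the preset correlation only. Of 24 acute phase and leukocyte recruitment genes 21 were lower, by a mean of -0.31 (limma camera adjusted p = 7.31e-06; adjusted p = 0.355 with an estimated correlation). Its leading members were Serpina3m (-0.90), Lrg1 (-0.67), Saa2 (-0.65) and the matrix protease Mmp7 (-0.58), of which Lrg1 and Mmp7 passed adjusted over the list alone. Of 22 antimicrobial and epithelial defence genes 18 were lower, by a mean of -0.37 (limma camera adjusted p = 9.87e-06; adjusted p = 0.438 with an estimated correlation). Only Reg3b passed adjusted over the list alone. The list mean was 0.38 in wild type 1 and 0.45 in wild type 2. It was -0.08 in the library labelled wild type 3 and -0.0017 in wild type 4, inside the ko range of -0.37 to 0.05. The call was lost without wild type 1 and 2, a choice made after seeing the data. Lcn2, which sequesters bacterial siderophores, differed by -0.85, the protease inhibitor Slpi by -0.58 and Ltf, encoding lactoferrin, by -0.35. Of 19 genes of regenerating (fetal-like) epithelium 16 were lower, by a mean of -0.23 (limma camera adjusted p = 1.00e-04; adjusted p = 0.355 with an estimated correlation). Msln (-0.76), the growth factor Areg (-0.59) and the urokinase receptor Plaur (-0.55) passed adjusted over the list alone, and Clu (-0.37) did not.

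Of 18 neutrophil genes 14 were lower, by a mean of -0.33 (limma camera adjusted p = 0.00120; adjusted p = 0.654 with an estimated correlation). The surface marker Ly6g had 8.91 ± 1.18 (SD, n = 4) in wild type and 7.56 ± 0.54 (SD, n = 4) in Arg1 ko, S100a9 differed by -0.69 (-0.39 without wild type 2) and G0s2 by -0.13. Passing adjusted over the list alone were 3 members, Lcn2 and Ltf, which the antimicrobial list also holds, and Ngp, named after its value was seen. Without wild type 2 the mean was -0.18, and the call was lost among genes with a mean of at least 5 (adjusted p = 0.0961) although the mean there was larger in size, at -0.42. Of 19 inflammatory cytokines and chemokines 17 were lower, by a mean of -0.20 (limma camera adjusted p = 0.00431; adjusted p = 0.654 with an estimated correlation), and none passed adjusted over the list alone. Cxcl2, Cxcl1, Osm and Ccl20 differed by -0.62, -0.57, -0.45 and -0.37, with Cxcl2 at -0.35 without wild type 2. Its call was lost without wild type 1 (mean -0.13, adjusted p = 0.0622), without the library labelled wild type 3 (adjusted p = 0.107) and among genes with a mean of at least 5 (mean -0.08, adjusted p = 0.487). The mean was -0.12 without wild type 2 and -0.35 without wild type 4.

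All 7 tested red blood cell genes were lower, by a mean of -0.73 (limma camera adjusted p = 9.44e-05; adjusted p = 0.542 with an estimated correlation), with none past adjusted over the list alone. Hbb-bs had 13.14 ± 0.91 (SD, n = 4) in wild type and 12.22 ± 0.31 (SD, n = 4) in Arg1 ko, and Bpgm, a red cell metabolic enzyme, differed by -0.34. Hba-a1 (-0.88) and Hba-a2 (-0.88) are near-identical copies between which reads cannot be assigned safely. The list mean ranged from -0.61 in the library labelled wild type 3 to 1.10 in wild type 1, and the difference was -0.49 without wild type 1.

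The lists of nuclear oxidative phosphorylation genes and of fatty acid oxidation were called lower at the preset correlation only, while those of the mitochondrial genome and of hypoxia and glycolysis did not pass. Of 32 nuclear genes of oxidative phosphorylation 30 were lower, by a mean of -0.21 (limma camera adjusted p = 7.31e-06; adjusted p = 0.748 with an estimated correlation), with none past adjusted over the list alone. Cox6c, Sdhd, Ndufa4 and Atp5c1, subunits of the respiratory chain and of ATP synthase, differed by -0.38, -0.35, -0.35 and -0.29. The list stood at 0.45 in wild type 1 and 0.24 in wild type 2, the 2 libraries with the highest ribosomal protein genes, and at -0.26 to 0.0010 in the other 6. Without both of these libraries the mean difference was 0.02. It was -0.10 without wild type 1, -0.34 without the library labelled wild type 3, -0.12 after quantile normalisation and -0.13 after the length and GC correction, the last chosen after seeing the data. Of 27 fatty acid oxidation and PPAR target genes 18 were lower, by a mean of -0.11 (limma camera adjusted p = 0.0220; adjusted p = 0.706 with an estimated correlation), with none past adjusted over the list alone. Angptl4 differed by -0.67, Acaa2 by -0.36, Acadl by -0.29 and Slc25a20 by -0.26. That call was lost without wild type 2 (mean -0.06, adjusted p = 0.156) and after quantile normalisation (adjusted p = 0.253).

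Of 20 genes of enteric neurons and glia 16 were lower, by a mean of -0.12 (limma camera adjusted p = 0.0142; adjusted p = 0.462 with an estimated correlation), none past adjusted over the list alone. Uchl1 differed by -0.52, the neuronal intermediate filament Prph by -0.29 and the neuropeptide Vip by -0.26. Erbb3, which epithelium also expresses, differed by -0.05, and by 0.06 after quantile normalisation. The call was lost without wild type 4 (adjusted p = 0.0564) and without Arg1 ko 2 (adjusted p = 0.0612). The immediate early and heat shock list, which responds to handling, had 17 of 26 members lower, by a mean of -0.14 (limma camera adjusted p = 0.0157; adjusted p = 0.542 with an estimated correlation). Past the test adjusted over the list alone were Klf2, Junb, Ier2, Ier3 (-0.49) and, in the other direction, the heat shock gene Hsph1 (0.58), named after its value was seen. The call was lost without the library labelled wild type 3 (adjusted p = 0.302) and without Arg1 ko 2 (mean -0.08, adjusted p = 0.122).

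**Figure D2:**
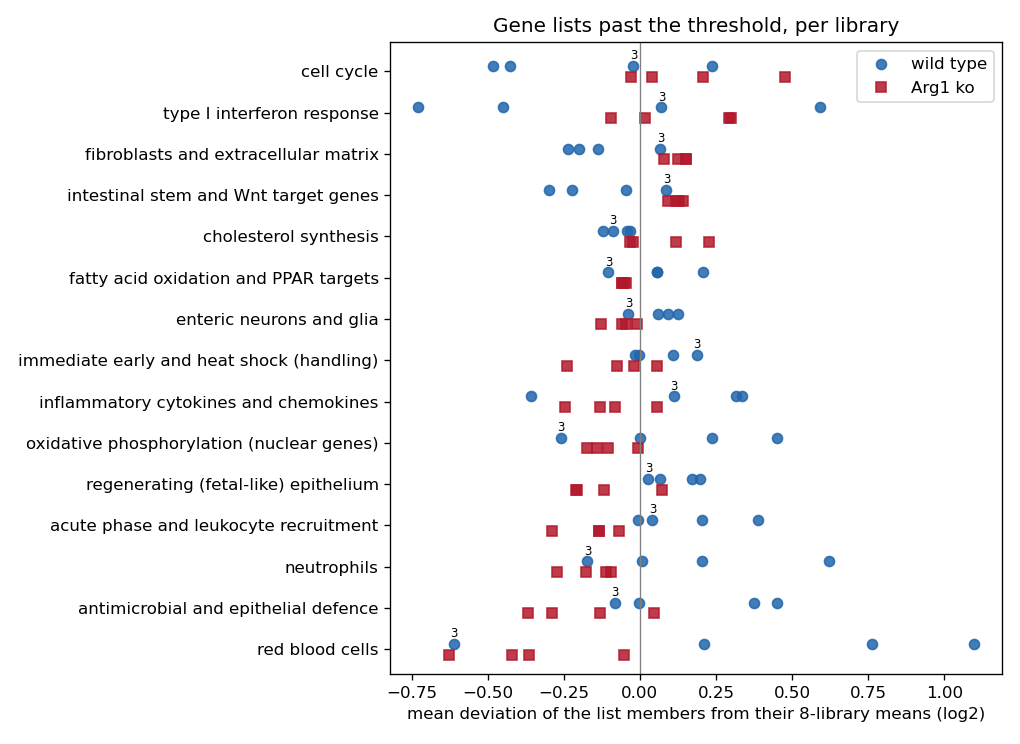
Mean deviation of each list's members from their means over the 8 libraries (log2, horizontal axis) for the 15 lists past the threshold; circles are the 4 wild-type and squares the 4 Arg1 ko libraries, and the digit 3 marks the library labelled wild type 3. The wild-type libraries spread from -0.61 to 1.10 for the red blood cell list, and the ko libraries from -0.63 to -0.05.

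The other 22 lists in the adjustment did not pass, with limma camera adjusted p from 0.0828 to 0.992 when all 8 libraries were used. Mean differences of cell type markers were -0.21 for B cells, 0.11 for smooth muscle, -0.13 for plasma cells and antibody, 0.09 for monocytes and macrophages and -0.05 for enteroendocrine and tuft cells. They were -0.0073 for endothelium, 0.13 for adipocytes, -0.01 for alternatively activated macrophages, 0.03 for mast cells and eosinophils, -0.0032 for T and NK cells and 0.0011 for pancreas and small intestine genes. Absorptive colonocyte genes differed by a mean of 0.04 and goblet cell and mucus genes by 0.04. Among pathways the means were 0.11 for ion and water transport, -0.17 for the circadian clock, 0.09 for the interferon gamma response and antigen presentation and -0.03 for tight junctions and barrier. They were -0.02 for xenobiotic metabolism and transport, 0.09 for the mitochondrial genome, -0.04 for the unfolded protein response and -0.01 for hypoxia and glycolysis. No member of these 22 lists passed adjusted over the list alone.

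Leaving out 1 library gave a call at the preset correlation to 8 of these 22 lists, that of arginine metabolism among them. With a correlation estimated from the same libraries, a combination tried after seeing the data, none of these calls nor those after quantile normalisation passed (adjusted p = 0.479 to 0.883 with an estimated correlation). Without wild type 1 the interferon gamma list was called higher (0.28, limma camera adjusted p = 2.72e-08), as was the monocyte and macrophage list (0.17, adjusted p = 0.0322), and the circadian clock list lower (-0.30, adjusted p = 0.00426). Without wild type 2 the lists of B cells (-0.34, adjusted p = 0.00133), plasma cells (-0.19, adjusted p = 0.0414) and the circadian clock (-0.22, adjusted p = 0.0391) were called lower and smooth muscle higher (0.13, adjusted p = 0.0167). Without wild type 4 the lists of T and NK cells (-0.18, adjusted p = 3.75e-04), B cells (-0.36, adjusted p = 0.00214) and plasma cells (-0.31, adjusted p = 4.81e-04) were called lower and smooth muscle higher (0.15, adjusted p = 0.0265). B cells were also called lower without Arg1 ko 1 (-0.25, adjusted p = 0.0285), and smooth muscle higher without Arg1 ko 3 (0.13, adjusted p = 0.0473). Of these lists, other single libraries turned the direction of all but smooth muscle. Without the library labelled wild type 3, which stood at 0.99 against -0.34 to 0.05 in the others, the B cell mean was 0.08 (adjusted p = 0.358). Without wild type 4, which stood at 0.76 against -0.32 to -0.03 in the others, the clock mean was 0.06 (adjusted p = 0.298). Without that library the interferon gamma mean was -0.05 (adjusted p = 0.298) and the monocyte and macrophage mean -0.03 (adjusted p = 0.512). Without wild type 1 the plasma cell mean was 0.01 (adjusted p = 0.993) and that of T and NK cells 0.10 (adjusted p = 0.137). After quantile normalisation the lists of smooth muscle (0.19, adjusted p = 6.04e-04), ion and water transport (0.16, adjusted p = 0.0104) and B cells (-0.23, adjusted p = 0.0363) passed.

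A single library or a correction also moved the differences of some named genes by over 1.5 times, among them Arg2 (-0.26) and Myh11 (0.29). Without wild type 1 those of Ndufa4, Hba-a1, Hba-a2 and Slc25a20 were -0.18, -0.52, -0.51 and -0.17, and that of Myh11 was 0.0054. Without wild type 2 those of Arg2 and Angptl4 were -0.13 and -0.44. Without the library labelled wild type 3 those of Hba-a1 and Vip were -1.33 and -0.40. Without wild type 4 those of Ephb3, Oas3, Dcn, Vip and Myh11 were 0.21, 0.32, -0.02, -0.17 and 0.53. After the correction for length and GC, Postn differed by 0.16, Cd44 by 0.19, Parp14 by 0.30, Ifih1 by 0.22, Dcn by -0.22, Myh11 by 0.15, Prph by -0.19, Sdhd and Ndufa4 by -0.22 each and Arg2 by -0.14. With length alone Ccl20 differed by -0.24 and Atp5c1 by -0.19. After quantile normalisation Sdhd differed by -0.23, Atp5c1 by -0.15, Slc25a20 by -0.16 and Dcn by -0.0059.

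The mean and the camera direction differed in sign for absorptive colonocytes, for pancreas and small intestine genes, for T and NK cells and for the sex-linked list. The median and the mean differed in sign for endothelium, alternatively activated macrophages, T and NK cells, mast cells and eosinophils, goblet cells and the sex-linked list. That list, kept out of the adjustment, had a mean difference of -0.07 over 5 genes, and its 4 Y-linked genes lay between 8.30 and 10.83 in all 8 libraries. Smooth muscle genes were among the most abundant transcripts in both groups, with Acta2 at 14.79 ± 0.23 (SD, n = 4) in wild type and 14.72 ± 0.09 (SD, n = 4) in Arg1 ko, Myh11 at 14.68 ± 0.65 (SD, n = 4) and 14.97 ± 0.11 (SD, n = 4), and Tagln and Tpm2 above 13 in all 8 libraries, although the protocol describes an epithelial preparation. Under quantile normalisation the differences of Acta2 and Tagln turned positive.

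The wild-type libraries differed more from each other than the ko libraries did. Over the tested genes the mean Euclidean distance was 58.8 within wild type, 26.4 within Arg1 ko and 47.9 between the groups. The groups were not separated beyond chance, since 3 of the 35 splits into 4 and 4, the real one included, gave a distance between minus within groups as large as the observed 5.38 (one-sided exact p = 0.0857). Without the library labelled wild type 3 the value was 17.1, the largest of 35 splits (one-sided exact p = 0.0286). That library was the wild-type one nearest to the ko libraries by the same distance. Leaving it out enlarges the value by construction, so that p-value is no independent check of the separation. The value was negative without Arg1 ko 4 (-0.90) and without Arg1 ko 1 (-0.51). The difference in spread between the groups, not among the tests fixed in advance, was the largest of the 70 assignments in either direction (exact permutation p = 0.0286, the smallest possible). The library labelled wild type 3 lay at a mean distance of 30.9 from the ko libraries and 60.7 from the other wild-type libraries. The other wild-type libraries were also nearer to the ko libraries than to their own group, by smaller margins, with 59.2 against 61.8 for wild type 1, 47.2 against 50.6 for wild type 2 and 54.5 against 61.9 for wild type 4. With the tested genes in 5 equal groups by length, the median deviation of the longest minus that of the shortest was -0.70 in wild type 1 and -0.38 in wild type 2, against 0.32 in the library labelled wild type 3, 0.17 in wild type 4 and 0.04 to 0.27 in the ko libraries. This measure did not differ between the genotypes beyond chance (exact p = 0.371). Across genes, which are not independent replicates, the ko minus wild type difference correlated with log2 transcript length at r = 0.39. Ribosomal protein genes, with short transcripts, had a mean of 13.92 in wild type 1 and 13.67 in wild type 2, and 12.90 to 13.38 in the other 6 libraries. Genes of oligodendrocyte-lineage glia and astrocytes, chosen after the principal components had been seen, averaged 6.37 in wild type 1 and 4.15 to 4.52 in the others. Glia markers listed before their values were seen averaged 6.75 in wild type 1 and 6.01 to 6.17 in the others. Genes of the Per and Dbp clock phase, also listed after the components had been seen, averaged 9.97 in wild type 4 and 8.49 to 8.85 in the others.

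**Figure D3:**
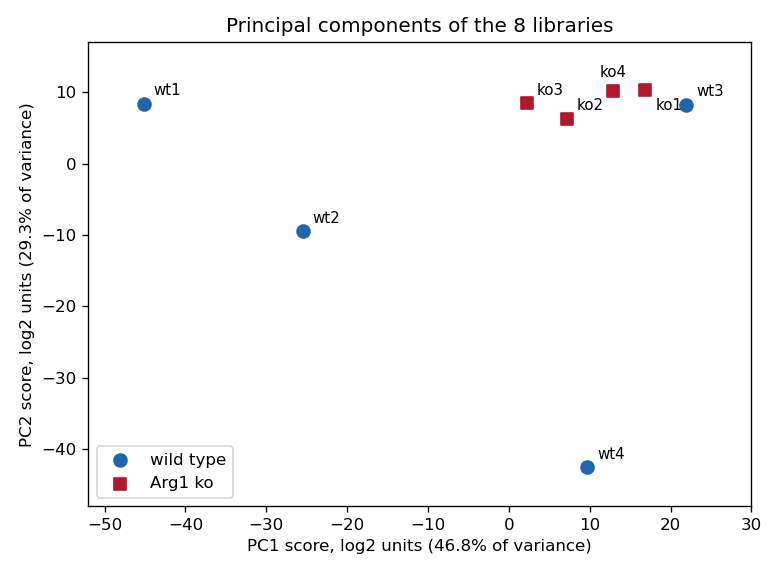
Scores of the 8 libraries on the first and second principal components of the rlog values of the tested genes (log2 units; 46.8% and 29.3% of the variance), wild type as circles and Arg1 ko as squares, each with its number. On the first component the ko libraries lie within 2.21 to 16.9 and the library labelled wild type 3 at 21.9. Wild type 1 and 2 lie away from them there, at -45.2 and -25.5. Wild type 4 lies inside the ko range on the first component (9.68). It is apart on the second, at -42.5 against 6.32 to 10.3 in the ko libraries.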

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

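The tests on wild type 1, those of the list calls after the length and GC correction, that of the position after the correction and the count of splits for all 8 libraries were chosen after the results were seen. The others had their outcome stated first, though the closeness of the library labelled wild type 3 to the ko libraries and its Arg1 value were already known. Among 228 groups of 4 values, 7 had an end value far from the other 3. That is a smaller share than the about 1 in 20 groups that chance gives. Of the 7, 4 were in the library labelled wild type 3, but values of the same library are not independent.

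In that library Arg1 was lowest of the wild type at 5.02 (next 5.57), Prph lowest at 8.99 (next 9.44), Col1a2 highest at 11.94 (next 11.53) and the hypoxia and glycolysis list lowest at -0.078 (next 0.026). This library lies near the Arg1 ko libraries over the whole transcriptome, for which a wrong genotype label is a candidate explanation. On an axis from the other wild-type libraries (0) to the ko libraries (1), over genes chosen without it, the library lay at 1.11, where ko libraries left out in turn lay at 0.79 to 1.09. Wild type 1, 2 and 4, each left out in turn, lay at 0.40, 0.18 and 0.78. The library labelled wild type 3 was left out of every axis. The axis for wild type 4 thus had only wild type 1 and 2 on its wild-type side, those lowest in the length measure. Wild type 4 had a wild-type level of Arg1, so a position near the ko libraries does not fix the genotype. Reg3b and Klf2 of the library labelled wild type 3 lay on the wild-type side, but they were chosen with it in that group. After the length and GC correction its position was 1.05 (ko libraries 0.78 to 1.04), which argues against that trend as the whole cause, while the calls made without it went from 1005 to 632, 421 of them shared, so a part for the trend stays open, as do a milder colitis in this mouse and handling in the order of the sample numbers, both untested.

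Without the library labelled wild type 3, 1 of the 35 splits of the 7 libraries, the real one, called as many as the 1005 genes, and the highest of the others called 0. At an unadjusted p under 0.05 the real split gave 4606 genes and the highest of the others 3677, so the real split was ahead by less there. For those 7 libraries taken alone the real split thus went beyond all others, but 1 of 35 is the smallest share that these splits can give. The splits also mix libraries of unlike spread, with a median SD of 0.258 in wild type and 0.096 in Arg1 ko over all 8 libraries. Chance is therefore not firmly excluded for the 1005 genes. Nor is it for the choice of the library left out, which was 1 of 8 and was known to lie near the ko libraries. With all 8 libraries every one of the 35 splits called 0 genes, so the count of 0 says nothing against chance; at an unadjusted p under 0.05, 7 of the 35 splits gave at least the 1490 genes of the real one, the highest of the others 4029. That split and 3 others with as many set wild type 1, 2 and 4 with a ko library against the rest, which a genotype difference with a wrong label could also give, while 2 set wild type 1 and 2 with 2 ko libraries (3263 with ko 2 and 3, 2396 with ko 3 and 4), which such a label would not explain; the 3263 split holds the 4 libraries lowest in the length measure.

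Wild type 1 carried genes of oligodendrocyte-lineage glia and Xist, the transcript of the inactive X chromosome of females. Of 25 glia markers listed before their values were seen, 10 are expressed by the other colon libraries at a mean of 6 or more. All 13 of the measurable weaker ones were highest in wild type 1 (Lhfpl3 5.01 against 2.49 to 3.12). With the abundant ones included, 15 of 23 measurable markers were. The abundant Mbp exceeded the mean of the other libraries by 0.10, at a level in the others (10.78 to 10.97) that would hide a small share. Most abundant markers were not highest there, and Cspg4 was lowest (8.36 against 8.73 to 8.96). Xist was at 6.31 against 3.22 to 3.98, an excess of 2.79, while the Y-linked Ddx3y was at 9.49, which argues against more enteric glia of the same male mouse. Markers of brain neurons had a median excess of -0.019, which argues against whole brain tissue. RNA of glial cells from a female source, mixed in at some step, may account for both; a sort or gate that would remove such cells is not described.

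The list calls between the genotypes may reflect the transcript length trend or the spread of the wild-type libraries. After the length and GC correction 13 of the 15 lists passed at the preset correlation. After length alone 12 did, without the stem cell list, whose limma camera adjusted p was 0.0497 with GC added. The means of the 13 lists moved by less than the standard errors before the correction. For the interferon list this could not have failed, since its mean (0.26) was below its standard error (0.31). For the other lists it argues against the trend, as fitted by the splines, as their whole cause, but not equally. The fibroblast mean after the correction was 0.19 (standard error 0.04). Little is said for lists whose remaining mean is not far above its error. Among these were oxidative phosphorylation (-0.13, standard error 0.09), neutrophil (-0.26, 0.15) and stem cell genes (0.17, 0.095). A part of the trend that the splines miss would also remain. Of the 13 lists the oxidative phosphorylation mean shrank most in proportion, from -0.21 to -0.13. The inflammatory cytokine mean went from -0.20 (standard error 0.17) to -0.12 (0.13) and the immediate early mean from -0.14 (0.08) to -0.11 (0.10); both calls ended with smaller means. Their median ratio was 0.677, just above a limit of 2 in 3 that belongs to a test chosen after the results were seen. Within these errors a part for the trend cannot be told apart from none, a condition added once the ratio was seen. Chance cannot be excluded for the number of calls: 11 of the 35 splits called at least 15 lists, the highest of the others 22, and a difference between genotypes stays open beside it.

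The remaining values far from their group were Cxcl2 in wild type 2 (5.74, next 4.72), Ltf in Arg1 ko 2 (4.79, next 4.70) and the goblet cell and mucus list in Arg1 ko 2 (-0.086, next 0.048).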

How the results depend on the processing

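The corrections for transcript length or for length and GC, and the fits without wild type 1 and 2 or without wild type 1 and 4, were chosen after seeing the data. No gene passed limma's threshold with 8 libraries (1490 at an unadjusted p under 0.05) or under 19 of 21 alternatives. The exceptions were array weights (10836 genes) and leaving out the library labelled wild type 3 (1005), so that leaving out 1 library gave 0 to 1005. Arg1 kept its sign in all 17 alternatives, with adjusted p from 1.51e-04, under the array weights that did not converge, to 0.872. It was -0.48 with array weights, and from -0.51 without the library labelled wild type 3 to -0.31 without Arg1 ko 2. The separation of the groups ranged from -0.90 without Arg1 ko 4 to 17.1 without the library labelled wild type 3. The number of lists past the threshold was 0 with an estimated correlation and 0 with fry, and stayed within 1.5 times of 15 in the other 18 alternatives with 1 choice changed. It was 0 with an estimated correlation in every fit without 1 library and after quantile normalisation, combinations tried after seeing the data. Of 1286 comparisons of named genes with an alternative 1154 kept direction and side of the threshold, 110 crossed it in the same direction and 22 changed sign. Of 629 for lists, 506 kept both, 26 lost and 29 gained a call, and 68 changed sign. The sex covariate was not run, since no group held both sexes. Unknown depth leaves open how much of the missing calls is due to counting noise, most for weakly expressed genes.

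The following changed sign, and the cause was not tested. With array weights the lists of absorptive colonocytes (-0.060), goblet cells and mucus (-0.14), B cells (0.14), plasma cells and antibody (0.088), mast cells and eosinophils (-0.021), endothelium (0.015) and pancreas and small intestine (-0.067) did, as did Nos2 (0.41), Odc1 (-0.011), Dcn (0.031) and Erbb3 (0.084). After the length correction these were the lists of enteroendocrine and tuft cells (0.015), alternatively activated macrophages (0.026), T and NK cells (0.053) and xenobiotic metabolism (0.0088), and G0s2 (0.030). With GC added they were 0.019, 0.025, 0.050 and 0.0029, with G0s2 at 0.036. Quantile normalisation turned the lists of pancreas and small intestine (-0.014), xenobiotic metabolism (0.026), tight junctions (0.045) and hypoxia (0.034), and Erbb3 (0.061), Tagln (0.050) and Acta2 (0.0017). With library medians aligned the mast cell list was at -6.8e-04 and the pancreas and small intestine list at -0.028. The latter was at -0.050 with a mean of at least 5, and the T and NK cell list at 1.2e-04 with no filter.

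Without wild type 1 and 2 the lists of arginine metabolism (0.064), enteroendocrine and tuft cells (0.017), alternatively activated macrophages (0.087), T and NK cells (0.17), inflammatory cytokines (0.022), hypoxia (0.019), the unfolded protein response (0.0017), oxidative phosphorylation (0.023) and the mitochondrial genome (-0.15) changed sign. So did G0s2 (0.24), Tpm2 (0.058), Myh11 (-0.15), Tagln (0.092) and Acta2 (0.032). Without wild type 1 and 4 these were the lists of mast cells (-0.0017) and hypoxia (0.012), Erbb3 (0.038) and Acta2 (0.0074).

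Leaving out 1 library at a time turned further values, with these ranges. Genes were Erbb3 (-0.24 to 0.20), G0s2 (-0.35 to 0.13), Nos2 (-0.22 to 0.25) and Odc1 (-0.037 to 0.19). Immune and stromal lists were B cells (-0.36 to 0.082), T and NK cells (-0.18 to 0.10), adipocytes (-0.032 to 0.27), alternatively activated macrophages (-0.081 to 0.033), endothelium (-0.075 to 0.035), mast cells (-0.014 to 0.066), monocytes and macrophages (-0.026 to 0.17) and plasma cells (-0.31 to 0.011). Epithelial lists were absorptive colonocytes (-0.060 to 0.12), goblet cells (-0.050 to 0.11), tight junctions (-0.055 to 0.0022) and pancreas and small intestine (-0.095 to 0.085). Pathway lists were arginine metabolism (-0.080 to 0.012), the circadian clock (-0.30 to 0.061), hypoxia (-0.042 to 0.0079), the interferon gamma response (-0.051 to 0.28), the mitochondrial genome (-0.024 to 0.19) and xenobiotic metabolism (-0.060 to 0.0077).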

Other observations

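The lists in this part, apart from that of B cells, were written after the principal components had been seen, and some of their genes had been seen among the leading ones. Wild type 4 had the highest value of all 10 genes of the Per and Dbp phase of the circadian clock. Ciart, a repressor of the clock, was at 8.88 there and at 5.74 to 6.33 in the other 7 libraries, Per1 at 11.76 against 9.54 to 10.30 and Nr1d1 at 11.83 against 10.43 to 10.73. Of the clock genes of the opposite phase, Npas2 was lowest in wild type 4 (9.04 against 9.40 to 9.77) and Arntl too (9.38 against 9.41 to 9.82), while Nfil3 was highest (10.28 against 8.78 to 9.82), Cry1 was level with the highest of the others (9.19 in wild type 4 and in the library labelled wild type 3) and Clock lay within their range (10.76 against 10.24 to 10.98). In the same library 13 of 15 glucocorticoid target genes were highest, with a mean of 12.22 against 11.06 to 11.67, and wild type 2 was second. Among them, Klf9 was at 12.36 against 10.01 to 11.19, Sgk1 at 14.85 against 13.38 to 14.25 and Zbtb16 at 10.25 against 7.51 to 9.44. The labels give no time of day, and no explanation was tested.

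Genes typical of other tissues were high in single libraries. In the library labelled wild type 3, 9 of 10 skeletal muscle genes were highest, among them the fast myosin Myh4 at 6.05 against 2.56 to 2.97 and Atp2a1 at 6.07 against 2.79 to 3.39, while Ckm was not (9.46 against 9.23 to 9.68). The B cell list stood at 0.99 in that library and at -0.34 to 0.05 in the others. In Arg1 ko 4, 11 of 12 exocrine pancreas genes were highest, among them Ctrb1 at 5.45 against 2.95 to 3.81 and Pnlip at 4.78 against 2.40 to 2.92.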
